A study of Mus musculus with 5 samples.

How the data were processed

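Bone marrow cells of B6 mice were profiled by droplet-based single-cell RNA sequencing (inDrops). After red cell lysis and depletion with antibodies to CD3e, CD19, Gr1, Mac1 and Ter119, 5 populations were sorted from lineage-negative, Kit-positive, Sca1-positive cells. These were LT-HSC (CD150-positive, CD48-negative), ST-HSC (negative for both), MPP2 (Flt3-negative, positive for both), MPP3 (Flt3-negative, CD150-negative, CD48-positive) and MPP4 (Flt3-positive, CD48-positive). There is 1 library per population, 5 in all. The deposited files hold UMI counts per cell and gene, with 28205 gene columns, which the authors made after mapping with Bowtie 1.1.1 to GRCm38. The deposited files also hold a column that marks cells passing a filter of the authors, whose rule is not stated.

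All 4941 deposited cells were used in the main analysis, and their number per library equals the stated number. The libraries hold 4000814, 2916979, 2550938, 5266587 and 3848409 UMIs (LT-HSC, ST-HSC, MPP2, MPP3, MPP4), so that a single UMI is 0.19 to 0.39 CPM. Genes from mitochondrial DNA make up 5.89%, 5.42%, 4.57%, 6.16% and 4.56% of UMIs. The authors' filter passes 789, 742, 663, 1089 and 965 cells, with between 1001 and 9925 UMIs each. Of 26399 gene symbols with at least 1 UMI, 94.7% were found by symbol in GENCODE M21, and coordinates come from there.

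For each library the UMIs of all cells were summed and scaled to CPM, counts relative to a common library total. A ratio between 2 libraries has an exact conditional binomial 95% interval, and a share of cells has a Clopper-Pearson interval. A count of 0 was taken to allow up to 3 counts. With 1 library per population there is no measure of variation between animals, so no test of difference was made, and a gene is called higher or lower when its ratio passes 1.5-fold. Before the data were examined, 24 gene lists with 331 genes, 326 of them in the files, were fixed from textbook knowledge. They cover the sort genes, stem cells, megakaryocyte, megakaryocyte-erythroid, erythroid progenitor, red cell, granulocyte-monocyte, early lymphoid, B cell, T and NK cell, dendritic, basophil with mast cell and eosinophil, mature neutrophil, macrophage and monocyte, and stroma and endothelium markers. The others are S phase, G2/M phase, cell cycle inhibitors, immediate early, heat shock, interferon response, ribosome biogenesis, glycolysis and nuclear-encoded respiratory chain genes. A list is given as the median log2 ratio of its members with at least 10 UMIs in the libraries compared, after 0.5 UMI was added to each count. Its interval comes from 1000 Poisson redraws, and its percentile from 10000 random lists of genes of like abundance, drawn among the 100 genes on either side of each member. Each MPP population was also compared with the mean of the other 2.

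Genes named in the text follow a rule. They are the 5 sort genes, the 8 highest and 8 lowest genes of each population against LT-HSC and the 8 highest of each MPP population against the other 2, among genes with at least 50 CPM in a library compared, and up to 4 genes of each list with at least 25 CPM in a library and the largest ratios. Sort genes, genes from mitochondrial DNA, ribosomal protein genes and gene models without a proper name were left out of the highest and lowest. A few genes beyond this rule are named for classes of cells.

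Cells of all libraries were clustered together with leidenalg 0.10.2, on a graph of nearest neighbours weighted by the share of neighbours that both cells have in common (Jaccard index). Counts were scaled per cell and log-transformed, and 2000 variable genes were picked in 20 bins of the mean among genes seen in at least 10 cells, without the sort genes, the S phase, G2/M phase and immediate early lists, and the mitochondrial and ribosomal protein genes. Values were limited to a z-score of 10, and 30 principal components, 15 nearest neighbours and a Leiden resolution of 1 were used. A cluster took the name of the list with most members among its 20 highest genes by fold, with at least 3 members, more than any other list, and no list with more among the first 10. The marker lists were fixed before, but this naming rule was set after the clusters had been seen. So was the rule that a cluster is low in Kit when its Kit CPM lies under 0.5 of the 249 CPM of all cells, which holds for 9 clusters with 576 cells, 11.7% of the total. Shares of cells with a UMI were taken after each cell had been thinned at random to 1000 UMIs, with shallower cells left out. Scrublet, run per library within Scanpy 1.11.5, called 76 doublets (1.54%), which stayed in the main analysis.

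Alternatives planned before the data were examined were a minimum of 1500 UMIs, a maximum of 5% mitochondrial UMIs, removal of called doublets, the mean of each cell's CPM, median-of-ratios size factors, CPM without mitochondrial, ribosomal protein and globin genes, other minimums for list members, resolutions of 0.5 and 2, 15 principal components, other sets of variable genes, thinning before clustering, thinning to 2000 UMIs and a minimum of 2 UMIs. The authors' filter, the removal of clusters low in Kit, the restriction to HSC-like cells and the alternatives for the MPP populations against each other were added after the data had been seen. Median-of-ratios size factors shift the log2 ratios to LT-HSC by −0.00, 0.06, 0.19 and 0.10 in ST-HSC, MPP2, MPP3 and MPP4.

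The methods were tested on simulated data. Intervals covered the simulated ratio for 95.4% to 95.8% of genes, all simulated changes of 2-fold and 4-fold passed the size rule and no unchanged gene did, and of lists without a simulated change 1.5% to 7% lay above the 95th percentile. The simulated library sums were Poisson draws, and ratios were checked at genes of at least 50 CPM. They leave out UMIs gathered in few cells, so they cannot show that the intervals hold for genes carried by small classes. Clustering of 800 cells simulated from 3 profiles gave 3 clusters with 100% of cells in the right one. These profiles differed strongly in many abundant genes, and their cells varied by random draws of UMIs alone. The result thus cannot show that classes that grade into each other are parted well. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9 were used.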

Results

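Long-term haematopoietic stem cells (LT-HSC), short-term stem cells (ST-HSC) and the multipotent progenitors MPP2, MPP3 and MPP4 of mouse bone marrow differ in the lineage genes they carry. The LT-HSC library is rich in stem cell and megakaryocyte transcripts, MPP2 in megakaryocyte and erythroid transcripts, MPP3 in granulocyte and monocyte transcripts, and MPP4 in early lymphoid transcripts. MPP2, MPP3 and MPP4 also hold groups of cells with little Kit RNA, several of them with the transcripts of mature blood cells. Each group is small, but the clusters low in Kit together hold 18.0% of MPP2, 22.9% of MPP3 and 9.15% of MPP4. They hold 1.17% of LT-HSC and 2.15% of ST-HSC. There is 1 library per population, so the intervals in brackets below are 95% intervals for counting error alone and carry nothing about differences between animals.

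The libraries hold 940 LT-HSC, 837 ST-HSC, 776 MPP2, 1372 MPP3 and 1016 MPP4 cells, with median depths of 3936, 3151, 3021, 3329.5 and 3607.5 UMIs per cell. The 5 genes behind the sort gates were read first. Slamf1, which encodes CD150, stands at 46.5 CPM (counts scaled to a common library total) in LT-HSC and 19.99 CPM in MPP2, the CD150-positive gates, and at 2.06 CPM in ST-HSC, 1.90 CPM in MPP3 and 0.52 CPM in MPP4. Cd48, the other SLAM family gene of the gates, is 8.61-fold higher than in LT-HSC in MPP2 (6.10 to 12.4), 14.6-fold in MPP3 (10.6 to 20.7) and 17.3-fold in MPP4 (12.5 to 24.6), and 2.32-fold higher in ST-HSC (1.54 to 3.54), which was sorted as CD48-negative. Flt3, the cytokine receptor that marks MPP4, is 18.9-fold higher there (15 to 24.1). It is also 12.5-fold higher in ST-HSC (9.86 to 16), a population with no Flt3 gate, and 2.48-fold and 2.53-fold higher in the Flt3-negative MPP2 and MPP3. Kit, the stem cell factor receptor used in each gate, is 1.71-fold, 1.60-fold and 1.64-fold lower in MPP2, MPP3 and MPP4 than in LT-HSC and 1.15-fold higher in ST-HSC. Ly6a, which encodes Sca1, lies between 103 and 195 CPM in the 5 libraries. The median log2 ratio of the 5 sort genes to LT-HSC is 0.50 in ST-HSC, −0.42 in MPP2, 0.27 in MPP3 and −0.39 in MPP4, and that of MPP3 turns to −0.49 without the clusters low in Kit, among them a Jchain-led cluster with Ly6a at 2091 CPM.

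**Figure D1:**
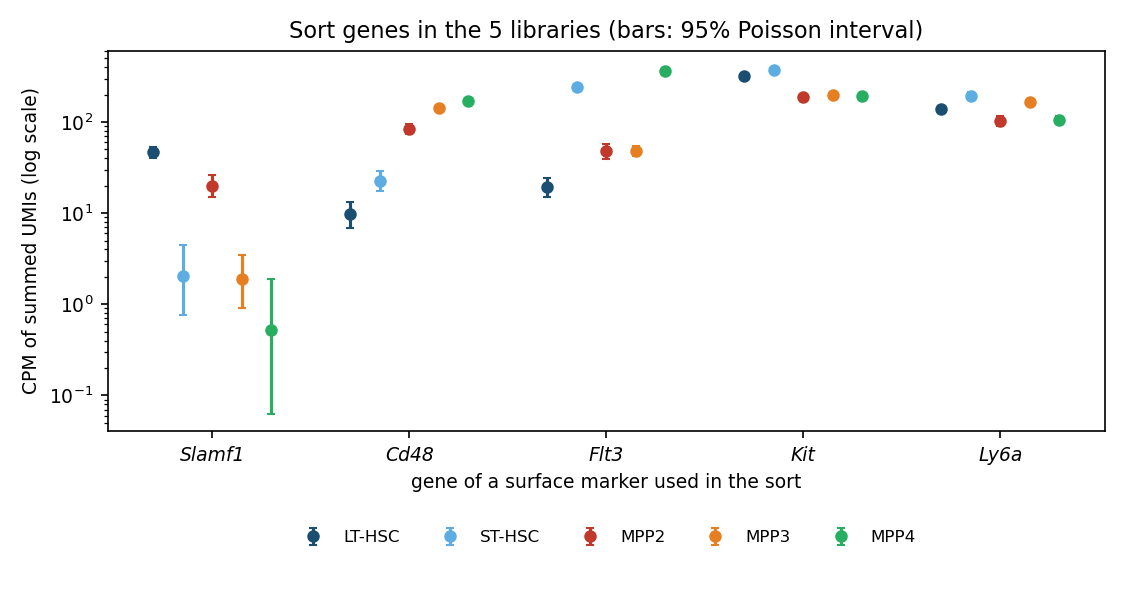
CPM of the 5 genes behind the sort gates in the 5 libraries. Bars are 95% intervals for counting error.

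ST-HSC and LT-HSC are the most similar pair with LT-HSC in it, with a Pearson correlation of 0.928 across 5106 genes, against 0.807 for LT-HSC and MPP3. ST-HSC carries less of the stem cell programme and far less of the megakaryocyte programme than LT-HSC. Early lymphoid genes are higher. Erythroid, red cell and mature neutrophil genes read higher too in the summed counts, but these lists lean on few cells. The 34 erythroid-like cells of ST-HSC hold 47.9% of its erythroid list UMIs. The erythroid and red cell lists fall with the authors' filter. The neutrophil list turns lower than in LT-HSC without the clusters low in Kit.

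Of 25 stem cell genes measured, 14 are lower and 2 are higher in ST-HSC by at least 1.5-fold, with a median log2 ratio of −0.67 (−0.82 to −0.59). Among them are Sult1a1, a sulphotransferase (5.60-fold lower, 3.84 to 8.42), Tgm2, the tissue transglutaminase (4.14-fold), Tcf15, a bHLH factor (3.27-fold), and Pdzk1ip1, a membrane protein gene of stem cells (2.01-fold). The megakaryocyte list lies lower still at −1.50 (−1.65 to −1.23), with 14 genes lower and 1 higher of 18 measured. Vwf, the von Willebrand factor of megakaryocytes and endothelium, is 16.6-fold lower (10.1 to 29.4), and Pf4, platelet factor 4, is 11.2-fold lower (8.51 to 15.1). Treml1, a platelet receptor, is 27.3-fold lower (10.5 to 102), Gp5, a glycoprotein of the von Willebrand factor receptor, 4.81-fold, Mmrn1, multimerin 1, 2.79-fold, and Itga2b, the platelet integrin αIIb, 4.85-fold (4.00 to 5.93). Other genes at the low end are Gda, guanine deaminase (7.45-fold), Apoe, apolipoprotein E (5.51-fold, 4.91 to 6.21), Aldh1a1, a retinaldehyde dehydrogenase (4.78-fold), and Tgfbr3, betaglycan (4.52-fold). The list shared by megakaryocyte and erythroid cells has a median of −0.30, with 2 of 8 genes lower, among them Gata2, a zinc finger factor of stem cells and mast cells (2.47-fold), and Zfpm1, the Gata1 partner FOG1 (1.99-fold).

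Early lymphoid genes are higher, with 8 of 14 past 1.5-fold, none lower and a median of 0.95 (0.70 to 1.14). Dntt, the terminal transferase of lymphoid progenitors, stands at 54.2 CPM against 1.5 CPM (36.1-fold, 16.2 to 99.9). Sell, L-selectin, is 5.85-fold higher (4.57 to 7.57), and Satb1, a chromatin organiser of lymphoid cells, 5.35-fold (4.30 to 6.72). Cd53, a leukocyte tetraspanin, is 15-fold higher (10.9 to 21) and Plac8, a gene of myeloid and lymphoid progenitors, 6.28-fold (5.74 to 6.86). Cebpa, a transcription factor of granulocyte and monocyte fate, is 5.52-fold higher (3.83 to 8.15), while the granulocyte-monocyte list as a whole is level, at −0.03 (−0.31 to 0.45), with 7 genes higher and 3 lower of 20. In LT-HSC a single granulocyte-monocyte-like cell, which fails the authors' filter, holds 25.9% of the UMIs of this list. Each comparison of the list with LT-HSC thus leans in part on 1 cell. In the cells that pass the authors' own filter the same list reads 0.84 in ST-HSC.

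The erythroid progenitor list is higher in ST-HSC at 1.68 (1.11 to 1.87), 11 of 16 genes higher and 1 lower, and the red cell list at 1.34, 6 of 9 higher, or 0.58 with the authors' filter. Hba-a2, an α-globin gene, is 18.7-fold higher (10.6 to 35.8), Mt2, a metallothionein, 10.3-fold (6.52 to 17.1), and Car1, the carbonic anhydrase of erythroid progenitors, 4.43-fold (3.68 to 5.35). Ter119 and red cell lysis were used to deplete red cells, yet 96.0% of the Hba-a2 UMIs and 97.47% of the Mt2 UMIs of ST-HSC sit in erythroid-like cells. With the authors' filter the erythroid list of ST-HSC reads 0.22, and Hba-a2 and Mt2 read 3.57-fold and 1.41-fold. Jchain, the joining chain of secreted immunoglobulin, is 77.8-fold higher (42.0 to 163), with 96.3% of its ST-HSC UMIs in a single Jchain-led cluster. It stands at 7.29 CPM rather than 194 CPM once clusters low in Kit are left out. The mature neutrophil list is higher as well at 1.34 (0.97 to 1.83), 5 of 8 genes, with Ltf, lactotransferrin, at 8.69-fold and Camp, cathelicidin, at 4.07-fold, despite depletion by Gr1 and Mac1. Without the clusters low in Kit that median is −0.89. Mature neutrophil-like cells number 2 in ST-HSC and 2 in LT-HSC, so the higher list goes with no difference in their number. A single gene of the basophil, mast cell and eosinophil list could be measured between ST-HSC and LT-HSC, so that list has no median there. Mitotic genes of the G2/M list are lower in ST-HSC, −0.57 (−0.60 to −0.40), 10 of 25 lower and 1 higher, with Aurka, the centrosomal kinase, 2.13-fold lower and Hmgb2, a chromatin protein, 1.67-fold higher. Within HSC-like cells alone the same list reads 0.13, but mitotic cells mostly lie outside that class, as the list is higher by 3.08 in the other LT-HSC cells. The S phase list is at −0.18, 1 of 20 lower, with Rrm1, a ribonucleotide reductase subunit, 1.94-fold lower.

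MPP2 shares its megakaryocyte genes with LT-HSC and adds an erythroid programme to them. The stem cell programme is low. Basophil and granulocyte-monocyte genes are high too. Most of the counts of the basophil proteases come from a small class of cells.

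The megakaryocyte list of MPP2 is level with LT-HSC at 0.04 (−0.13 to 0.26), 4 genes higher and 3 lower of 19. Within it Pf4 is 1.64-fold higher (1.48 to 1.80) and Gp5 2.16-fold, Treml1 is level, and Mmrn1 is 4.51-fold lower. Erythroid progenitor genes are higher, 14 of 16, none lower, with a median of 2.81 (2.40 to 3.14). Car1 stands at 836 CPM against 37.5 CPM (22.3-fold, 18.9 to 26.5), and 95.8% of its MPP2 UMIs lie in erythroid-like cells. Mt2 is 18.1-fold higher and Tspo2, an erythroid transporter of the mitochondrial translocator family, 14.5-fold. Gata1, the master factor of erythroid and megakaryocyte cells, is 3.57-fold higher (2.95 to 4.32), and the shared megakaryocyte-erythroid list reads −0.22, 1 of 8 higher. The red cell list is at 0.53, 4 of 9 higher and 2 lower, with Hbb-bt, a β-globin gene, 1.54-fold lower and Bpgm, the red cell phosphoglycerate mutase, 2.31-fold lower. That median is 0.22 with the authors' filter and 1.16 without the clusters low in Kit.

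Each of the 25 measured stem cell genes is lower in MPP2, with a median of −1.84 (−1.93 to −1.63). The lowest of the named genes are Pygm, glycogen phosphorylase (28.3-fold lower, 12.0 to 88.0), Sult1a1 (16.9-fold, 8.73 to 37.3), Col4a2, a basement membrane collagen (9.96-fold, 5.69 to 19.0), Tinagl1, a matrix protein (7.18-fold, 4.68 to 11.5), and Nkx2-3, a homeobox gene (6.59-fold, 4.79 to 9.27). Art4, an ADP-ribosyltransferase (6.46-fold), Iigp1, an interferon-inducible GTPase (6.42-fold), and Obsl1, a cytoskeletal linker (5.87-fold), follow.

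At the high end of MPP2 stand genes of basophils and mast cells. Prss34, a basophil protease, is at 842 CPM, against 2 UMIs in LT-HSC (1684-fold, 466 to 13918), and Mcpt8, the mouse basophil protease, is 322-fold higher (88.4 to 2664). Of these UMIs 91.1% and 93.7% lie in the basophil, mast cell and eosinophil-like class. Cpa3, the mast cell carboxypeptidase, is 39.0-fold higher (24.4 to 66.5), and Ms4a2, the β chain of the high-affinity IgE receptor, 31.8-fold (15 to 80.6). The basophil, mast cell and eosinophil list has a median of 5.28, with 7 of 7 genes higher. Jchain (453-fold, 246 to 945), Ccl3, a macrophage chemokine (33.2-fold, 19.9 to 60.1), and Dntt (34-fold, 15.2 to 94.3) are high in MPP2 too. In MPP2 the Jchain-led cluster holds 12 cells, the Ccl3-led cluster 5 and the lymphoid-like class 9. UMIs gathered in few cells are not taken into account by these intervals. The granulocyte-monocyte list is higher, 19 of 20 genes at 2.25 (2.04 to 2.53), led by Plac8 at 12.0-fold, Mpo, myeloperoxidase, at 7.12-fold and Ms4a3, a gene of granulocyte-monocyte progenitors, at 7.10-fold. It reads 1.40 without the clusters low in Kit, with 16 of 19 genes higher, and 37.9% of its MPP2 UMIs lie in granulocyte-monocyte-like cells. The mature neutrophil list is at 1.80 (7 of 8, Camp 12.8-fold) and the dendritic list at 1.22 (6 of 8, with Cd74, the invariant chain, 4.10-fold and H2-Eb1, an MHC class II chain, 3.54-fold). Without the clusters low in Kit these medians are 0.42 and −0.22. Early lymphoid genes show 5 of 13 higher and 2 lower, with a median of 0.08 (−0.07 to 0.36). G2/M genes are higher, 11 of 25 and none lower, at 0.54 (0.38 to 0.61), with Hmgb2 at 3.57-fold (3.36 to 3.80). Among cells with at most 5% mitochondrial UMIs, which keeps 308 LT-HSC and 600 MPP2 cells, the G2/M list reads 0.17 (−0.00 to 0.29), with 4 of 25 higher. The S phase list is at 0.29, with 1 of 20 genes past 1.5-fold, the replication licensing gene Cdc6 (2.31-fold).

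MPP3 carries the strongest granulocyte and monocyte programme of the 5 populations. Stem cell and megakaryocyte genes are low. Its highest single ratios belong to genes of a small Jchain-led cluster without a name, to Rhd of erythroid cells and to Prss34 of basophils. The scaling of MPP3 differs most between methods, since median-of-ratios size factors would add 0.19 to each log2 ratio below.

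All 20 measured granulocyte-monocyte genes are higher in MPP3 than in LT-HSC, with a median of 3.41 (3.02 to 3.66). Mpo stands at 1478 CPM against 57.7 CPM (25.6-fold, 22.5 to 29.3), Ms4a3 is 22.9-fold higher (16.4 to 32.8), Plac8 21.6-fold (19.96 to 23.5), and Ctsg, cathepsin G of primary granules, 20.04-fold (17.2 to 23.4). In LT-HSC only 5 Mpo UMIs lie in HSC-like cells and 4 in megakaryocyte-like cells. Most of the LT-HSC baseline of Mpo thus comes from its remaining cells, which the interval does not take into account. Among these is the single granulocyte-monocyte-like cell that holds 25.9% of the LT-HSC UMIs of the list. Mature neutrophil genes are higher at 2.47 (2.40 to 2.80), 7 of 8, with Camp 15.3-fold and Lcn2, lipocalin 2, 11.3-fold, against a depletion by Gr1 and Mac1. The median without the clusters low in Kit, the mature neutrophil-like one among them, is 0.46.

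Jchain is 1367-fold higher in MPP3 (743 to 2851), at 3416 CPM, and 99.1% of its UMIs lie in the Jchain-led cluster. Without the clusters low in Kit it stands at 16.3 CPM. The same cluster holds 97.8% to 99.4% of the MPP3 UMIs of Tff1, a trefoil peptide (239-fold, 42.5 to 9451), Mzb1, a chaperone of antibody-secreting cells (165-fold, 56.2 to 803), Ly6d, an early B lineage surface gene (144-fold, 49.1 to 701), and Pou2af1, the B cell co-activator OBF1 (60.9-fold, 29.4 to 152). It also holds 89.5% of those of Prg2, the eosinophil major basic protein (222-fold, 75.7 to 1079). The B cell list reads 0.49 in MPP3, 4 of 10 higher and 2 lower, with Cd79a, the signalling chain of the B cell receptor, 38.9-fold higher (15 to 144), and it reads −0.70 without the clusters low in Kit. CD19 was among the depletion antibodies. Rhd, the Rhesus blood group gene, has no UMI in LT-HSC and is at least 77.5-fold higher in MPP3, with 99.7% of its UMIs in erythroid-like cells. The erythroid progenitor list is higher at 2.42 (1.99 to 2.60), 12 of 16 genes higher and 2 lower, and Car1 is 11.4-fold higher (9.68 to 13.6). With the authors' filter the list reads 1.34 (0.96 to 1.69), 10 of 16 higher and 3 lower. The red cell list is at 0.94, 5 of 9 higher, and at 0.21 with the authors' filter. Prss34 is 327-fold higher (90.3 to 2705), and the basophil, mast cell and eosinophil list has 12 of 12 genes higher at 5.16. Dendritic genes read 0.80, 5 of 9 higher, and −0.50 without the clusters low in Kit. Lymphoid genes read 0.09 (−0.01 to 0.44), 6 of 15 higher and 3 lower, with Sell at 16.5-fold.

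The stem cell list is lower in MPP3 for 25 of 25 genes, −2.22 (−2.42 to −1.97), and the megakaryocyte list for 15 of 18, −1.99 (−2.20 to −1.70). Pf4 is 37.1-fold lower (25.6 to 55.7), Sult1a1 26.1-fold (14.7 to 51.2), Pygm 19.5-fold (11.6 to 35.4), Vwf 16-fold (11.0 to 24.1), Mmrn1 15.9-fold (12.0 to 21.4) and Tgm2 13.2-fold (10.5 to 16.7), followed by Art4 (10.5-fold) and Tinagl1 (8.97-fold). Gata2 is 2.10-fold lower, and the megakaryocyte-erythroid list reads −0.64, 1 higher and 4 lower of 8. G2/M genes are higher, 11 of 25, at 0.44 (0.39 to 0.59), with Bub1, a spindle checkpoint kinase, 2.26-fold higher, but 5 of 25 at 0.17 among cells with at most 5% mitochondrial UMIs. S phase genes are at 0.37, 4 of 20 higher, with Rrm2, the small ribonucleotide reductase subunit, 2.20-fold higher.

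MPP4 is the population of early lymphoid genes, and it also carries a granulocyte-monocyte programme. Megakaryocyte, megakaryocyte-erythroid and stem cell genes are low. Basophil protease genes are high in counts and come mostly from about 2 in 100 of its cells.

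Of 15 early lymphoid genes measured in MPP4, 11 are higher and 1 is lower, with a median of 1.56 (1.08 to 1.84). Dntt stands at 456 CPM against 1.5 CPM (304-fold, 139 to 829), Sell is 16.5-fold higher (13.2 to 21), and Satb1 10.9-fold (8.92 to 13.5). Cd53 is 31.6-fold higher (23.3 to 43.9), and Wfdc17, a secreted antiprotease of myeloid cells, 32.0-fold (18.9 to 59.0). The granulocyte-monocyte list is at 2.25 (2.04 to 2.63), 19 of 20 genes higher, with Plac8 at 20.3-fold, Mpo at 9.04-fold and Ctsg at 7.23-fold. Dendritic genes are higher, 8 of 10, at 1.60 (1.25 to 1.73), with H2-Eb1 3.77-fold and H2-Aa, an MHC class II chain, 2.53-fold, and the median without the clusters low in Kit is 0.33. Mature neutrophil genes are higher, 9 of 9, at 3.16 (2.58 to 3.52), with Ltf 17.1-fold and Lcn2 16.6-fold, and the median without those clusters is −0.47. Of the 1016 MPP4 cells, 7 are mature neutrophil-like. Gr1 and Mac1 were in the depletion mix for this population too.

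Prss34 (1436-fold, 397 to 11865), Mcpt8 (295-fold, 81.2 to 2440), Cpa3 (32.9-fold, 20.6 to 56.0), Jchain (115-fold, 62.3 to 240) and Ccl3 (26.9-fold, 16.1 to 48.5) complete the high end of MPP4. The clusters led by Jchain and by Ccl3 hold 5 MPP4 cells each. The intervals do not take into account UMIs gathered in few cells. The basophil, mast cell and eosinophil list has 8 of 8 genes higher at 4.82. Erythroid progenitor genes are mixed, 8 higher and 4 lower of 16, at 0.56 (0.22 to 0.91), and at 0.08 in cells that pass the authors' filter. The red cell list is at 0.26, 1 of 8 higher.

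The megakaryocyte list of MPP4 is the lowest of the 4 populations, −2.56 (−2.90 to −2.30), 15 of 19 genes lower and 1 higher. Pf4 is 71.4-fold lower (39.7 to 144), Treml1 36.1-fold, Mmrn1 19.6-fold (13.7 to 28.9) and Vwf 13.5-fold (9.07 to 21). The megakaryocyte-erythroid list has 7 of 8 genes lower, −1.40 (−1.55 to −1.14), with Gata2 3.98-fold, Zfpm1 4.75-fold, Gata1 3.14-fold and Gfi1b, a repressor of both lineages, 3.26-fold lower. Of the stem cell list 22 of 25 genes are lower, −2.27 (−2.39 to −1.97), among them Tgm2 (43.1-fold, 27.4 to 71.9), Sult1a1 (20.8-fold, 11.4 to 42.3) and Pdzk1ip1 (17.2-fold, 11.9 to 25.5). Phlda2, an imprinted gene (17-fold, 10.1 to 30.8), and Tinagl1 (16.6-fold, 9.88 to 30.1) are low as well. G2/M genes are higher at 0.58 (0.46 to 0.63), 11 of 25, with Nusap1, a spindle protein, 2.09-fold higher, but 3 of 25 at 0.20 among cells with at most 5% mitochondrial UMIs. S phase genes are at 0.48, 6 of 20 higher, with Ung, uracil glycosylase, 1.93-fold higher.

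**Figure D2:**
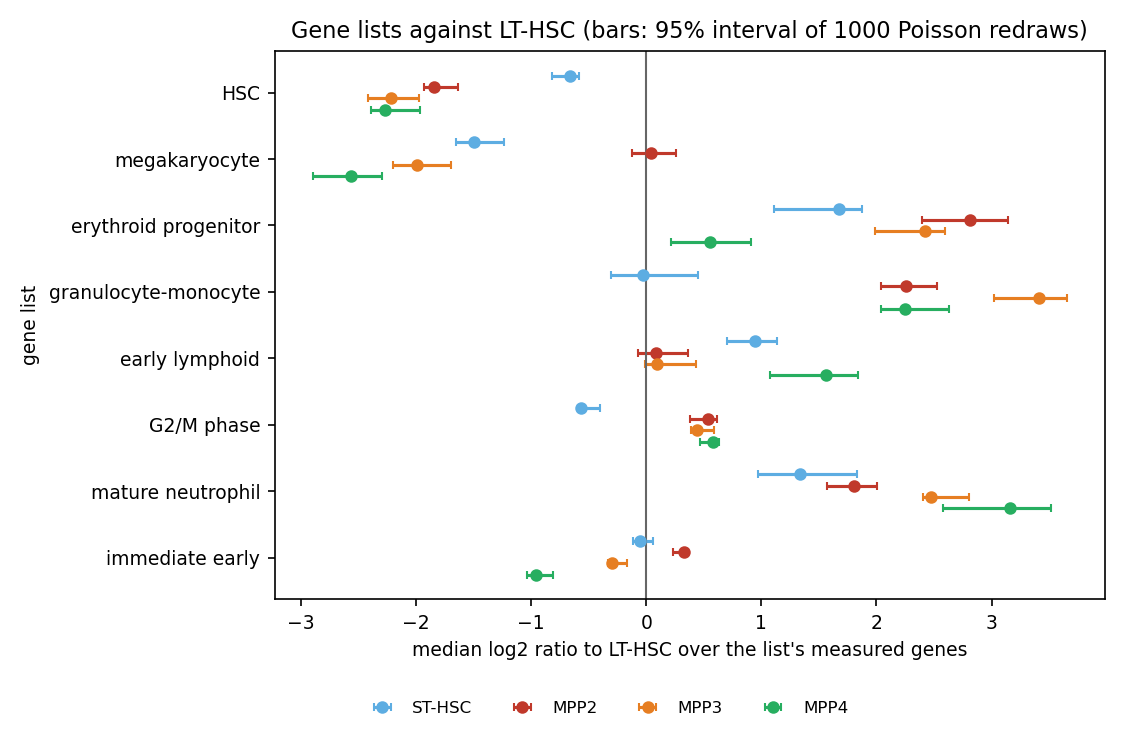
Median log2 ratio to LT-HSC of 8 gene lists in ST-HSC, MPP2, MPP3 and MPP4. Bars are 95% intervals of 1000 Poisson redraws of the counts.

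Set against each other, the 3 MPP populations separate along the lineages of their gates. MPP2 stands out by megakaryocyte genes, MPP3 by granulocyte-monocyte genes and MPP4 by lymphoid genes. Each was compared with the mean of the other 2.

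In MPP2 the megakaryocyte list is higher for 16 of 19 genes and lower for none, with a median of 1.95 (1.67 to 2.14). Pf4 leads at 79.9-fold (334 CPM against 4.18 CPM), followed by Samd14, an erythroid signalling gene (6.64-fold), Trib2, a pseudokinase (5.82-fold), F2r, the thrombin receptor PAR1 (5.53-fold), Tuba8, a tubulin of platelets and muscle (4.93-fold), Apoe (4.46-fold), Pbx1, a homeobox gene of stem cells (4.09-fold, 725 CPM against 177 CPM), and Itga2b (3.93-fold). The erythroid progenitor list of MPP2 is at 0.66 (0.56 to 0.83), 11 higher and 1 lower of 16. In MPP3 the granulocyte-monocyte list is at 0.89 (0.78 to 1.05), 14 higher and 1 lower of 20, with Elane, neutrophil elastase, at 3023 CPM against 617 CPM (4.90-fold) and Trem3, a myeloid receptor, at 6.89-fold. Ly6d (8.04-fold), Prg2 (7.25-fold), Tff1 (6.62-fold), Mzb1 (6.02-fold), Pou2af1 (5.98-fold) and Jchain (4.81-fold) complete the high end of MPP3, and they are the genes of the Jchain-led cluster named above. In MPP4 the lymphoid list is at 0.53 (0.47 to 0.93), 7 higher and 1 lower of 15, and at 1.15 without the clusters low in Kit. Dntt leads at 15.5-fold (456 CPM against 29.4 CPM), with Satb1 at 3.97-fold (279 CPM against 70.2 CPM), Wfdc17 at 7.33-fold, Il1r1, the interleukin 1 receptor, at 4.76-fold, Gpr171, an orphan receptor of lymphoid cells, at 4.03-fold, Il12a, the p35 chain of interleukin 12, at 3.55-fold, and Bex6, a brain-expressed X-linked family gene, at 3.45-fold. Ltf is 5.13-fold higher in MPP4, with 98.8% of its UMIs in 7 mature neutrophil-like cells, which Gr1 and Mac1 depletion is meant to remove.

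Clustering of the 4941 cells together gave 19 clusters. Classes of stem cell-like, megakaryocyte-like, erythroid-like, granulocyte-monocyte-like and lymphoid-like cells are found across the gates in different shares. Classes of mature cells appear mainly in the MPP gates.

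HSC-like cells, 1885 in all, make up 62.3% of LT-HSC (59.2 to 65.5), 75.0% of ST-HSC (72 to 77.9), 13.1% of MPP2, 25% of MPP3 and 22.2% of MPP4. After thinning to 1000 UMIs the order of LT-HSC and ST-HSC turns, to 67.7% and 52.3%, and MPP3 and MPP4 hold 9.94% and 5.98%. With no gene left out LT-HSC and ST-HSC hold 61.1% and 56.5% and MPP4 9.65%, and across the other settings MPP2 goes from 8.63% to 21.8%, MPP3 from 11.8% to 30.2%, and MPP4 from 11.6% to 41.0%. In the main clustering they fall into a Sult1a1-led cluster that holds 52.2% of LT-HSC and 10.3% of ST-HSC, and an Hlf-led cluster that holds 10.1% of LT-HSC and 64.8% of ST-HSC. The Sult1a1-led cluster holds 3.35% of MPP2, 0.44% of MPP3 and 0.30% of MPP4, and the Hlf-led cluster 9.79%, 24.56% and 21.95%. The HSC-like cells of MPP3 and MPP4 thus lie almost all in the cluster where most ST-HSC cells are. Hlf, a bZIP factor of stem cells, is 1.40-fold higher in the HSC-like cells of ST-HSC than in those of LT-HSC (1.31 to 1.48), whereas the stem cell list as a whole is lower there, −0.77, 16 of 25 genes. Within the same class Vwf is 17.9-fold lower in ST-HSC (9.81 to 36.4), Sult1a1 6.66-fold lower (4.56 to 10.03), Flt3 12.2-fold higher (9.04 to 16.7), Dntt 11.2-fold higher (4.89 to 31.8) and Cd34, a sialomucin of progenitors, 3.85-fold higher (3.42 to 4.33). Lymphoid genes read 0.81, 9 of 13 higher, and granulocyte-monocyte genes 0.75, 9 of 15 higher.

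Megakaryocyte-like cells are 22.0% of LT-HSC (19.4 to 24.8) and 24.1% of MPP2 (21.1 to 27.3), against 0.956% of ST-HSC, 2.11% of MPP3 and 0.295% of MPP4. The share depends on how cells are grouped. It is 9.53% of LT-HSC when each cell is thinned to 1000 UMIs first, 0.376% or 3.35% of ST-HSC with thinning or without the list genes, 13.7% of MPP2 without the list genes, and 1.09% of MPP3 when no gene is left out of the clustering. The megakaryocyte-like cells hold 47.1% of the megakaryocyte list UMIs of LT-HSC and 67.0% of those of MPP2. Of the 207 such cells of LT-HSC, 71 stay in the class after thinning, with Pf4 at 1404 CPM, while 78 move to a Pbk-led cluster with Pf4 at 157 CPM and Mki67, the proliferation antigen, at 295 CPM, 47 to the HSC-like class with Pf4 at 266 CPM, and 11 to a Dntt-led cluster. Of the 187 of MPP2, 97 stay, 73 move to the Pbk-led cluster and 4 to the HSC-like class. Between the megakaryocyte-like cells of MPP2 and of LT-HSC, Cd48 is 7.5-fold higher in MPP2 (3.83 to 16.1), Pf4 2.01-fold higher (1.81 to 2.22), Mecom, a stem cell zinc finger factor, 3.12-fold lower (1.85 to 5.57), and Mpl, the thrombopoietin receptor, 1.82-fold lower. Part of the Pf4 ratio goes with this split, since it is 1.46-fold (1.30 to 1.63) among the cells that stay and 1.44-fold (1.02 to 2.01) among those in the Pbk-led cluster. Mecom is 2.89-fold and 3.32-fold lower there, and Mpl 1.31-fold (1.05 to 1.64) and 2.41-fold (1.85 to 3.16) lower, so that Mpl does not pass 1.5-fold among the cells that stay. The stem cell list is at −0.91 between them, with 15 of 23 genes lower, and the megakaryocyte list at 0.48, with 6 of 17 higher.

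Erythroid-like cells are 22.2% of MPP2 (19.3 to 25.3), 6.49% of MPP3 (5.24 to 7.92), 4.06% of ST-HSC, 1.38% of MPP4 and 0.851% of LT-HSC. After thinning the MPP2 share is 10.1% and that of LT-HSC 0.222%, and with the authors' filter MPP3, ST-HSC and MPP4 hold 3.86%, 2.02% and 0.829%. In the main clustering they hold 75.6% of the erythroid list UMIs of MPP2 and 47.9% of those of ST-HSC. Granulocyte-monocyte-like cells are 14.1% of MPP3 (12.3 to 16), 5.02% of MPP4 and 3.09% of MPP2, with 0.106% and 0.119% in LT-HSC and ST-HSC. Without the list genes the MPP4 and MPP2 shares are 3.25% and 1.55%. Lymphoid-like cells are 16.1% of MPP4 (13.9 to 18.6), 2.15% of ST-HSC, 1.16% of MPP2, 0.292% of MPP3 and 0.213% of LT-HSC. No cluster earns the lymphoid name in 5 of the 8 other ways of clustering. With 15 principal components the class is 27.5% of MPP4, 13.4% of MPP3, 9.08% of ST-HSC, 5.28% of MPP2 and 1.17% of LT-HSC, so that it is less particular to MPP4. Basophil, mast cell and eosinophil-like cells, with Kit at 202 CPM, are 3.35% of MPP2, 3.57% of MPP3 and 1.97% of MPP4. Classes of mature cells include mature neutrophil-like cells (2.77% of MPP3), T and NK-like cells (2.96% of MPP2) and dendritic-like cells (1.80% of MPP2 and 1.97% of MPP4). No LT-HSC cell is in the basophil, mast cell and eosinophil, T and NK or dendritic classes, so each is below 0.319% there. CD3e was in the depletion mix, but the T and NK-like class was not parted into T and NK cells. Its leading genes include Klrc1 and Klre1 as well as Cd3g. The mix held no antibody against basophil or dendritic cell antigens other than Mac1. Of all cells 32.65% are in 8 clusters that no list names, the largest of them an Hbb-bt-led cluster of 679 cells and a Cep55-led cluster of 488 cells with mitotic genes, which holds 19.7% of MPP4 and 4.36% of LT-HSC.

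**Figure D3:**
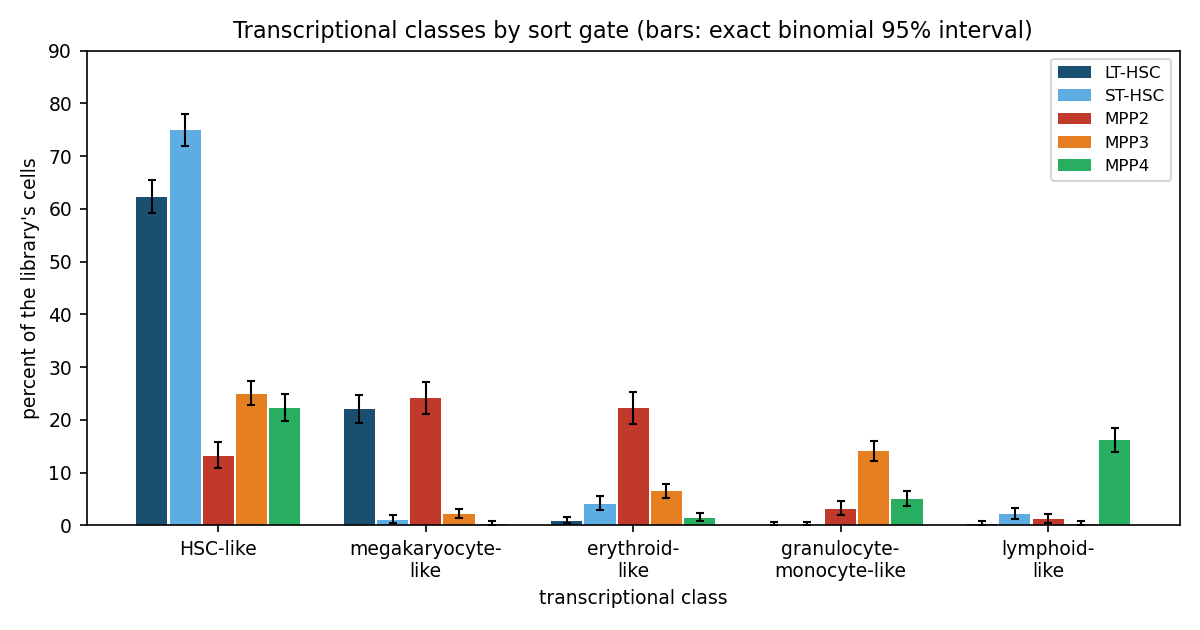
Share of each library in the cell classes named from fixed marker lists. Bars are 95% Clopper-Pearson intervals.

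Counting cells with at least 1 UMI shows how each programme is spread. Cells were thinned to 1000 UMIs so that depth is equal, which leaves out 38, 39, 75, 104 and 12 cells of LT-HSC, ST-HSC, MPP2, MPP3 and MPP4. Most lineage genes are then seen in a minority of the cells of a gate.

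Any gene of the G2/M list is seen in 58.7% of LT-HSC (55.4 to 61.9) and 58.4% of ST-HSC (54.9 to 61.8), and in 77.2% of MPP2, 72.8% of MPP3 and 74.5% of MPP4 (71.7 to 77.2). Without thinning the shares are 86.3%, 83.4%, 88.0%, 85.7% and 92.4%. Asking for 2 UMIs instead of 1 lowers them to 31.9%, 32.2%, 56.1%, 53.3% and 54.3%. Pf4 is seen in 7.65% of LT-HSC and 8.70% of MPP2 after thinning, and in 1.13%, 0.63% and 0.20% of ST-HSC, MPP3 and MPP4. It is in 25.6% of the megakaryocyte-like cells of LT-HSC (median depth 5749 UMIs before thinning) and 1.90% of its HSC-like cells (3772 UMIs), and in 0.53% of the granulocyte-monocyte-like cells of MPP3 (5669 UMIs), which should lack it. Vwf is seen in 5.43% of LT-HSC and 0.63% of ST-HSC, and in 0.606% of the erythroid-like cells of MPP2 (3505 UMIs), which should lack it. Dntt is seen in 20.9% of MPP4, 3.63% of ST-HSC and 0.22% of LT-HSC, and in 64.6% of the lymphoid-like cells of MPP4 (3442 UMIs), against 0.53% of the granulocyte-monocyte-like cells of MPP3 (5669 UMIs). Mpo is seen in 30.2% of MPP3, 21.2% of MPP4 and 8.85% of MPP2, whereas Elane is in 18.9% of MPP3 and 3.79% of MPP4. Mpo is in 94.1% of the granulocyte-monocyte-like cells of MPP3, and in none of its 86 thinned erythroid-like cells (6993 UMIs), which limits cells with an Mpo UMI at this depth to 3.49%, and Elane is in 86.1% and 1.16% of the same classes. Car1 is seen in 18.8% of MPP2 and 6.94% of MPP3, in 70.3% of the erythroid-like cells of MPP2 (3505 UMIs) and in 0.61% of the lymphoid-like cells of MPP4 (3442 UMIs). Hlf is seen in 40.9% of LT-HSC, 58.4% of ST-HSC and 16.4% of MPP2, and Mecom in 16.4%, 10.4% and 3.14% of the same populations. In the granulocyte-monocyte-like cells of MPP3 (5669 UMIs) Hlf is still seen in 5.35%.

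**Figure D4:**
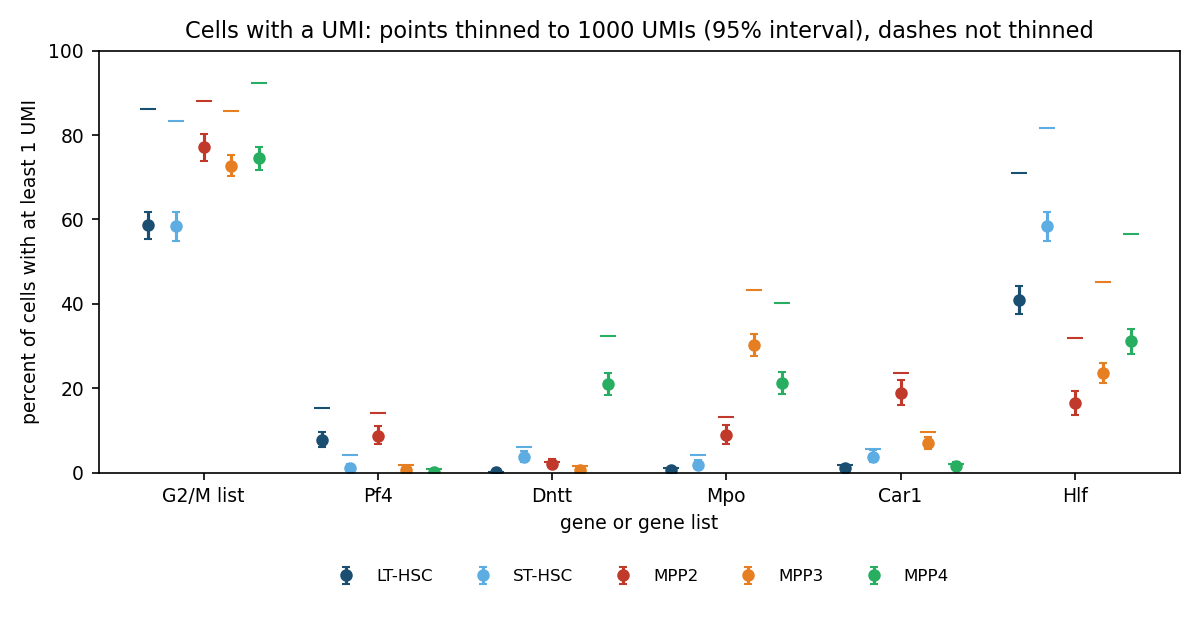
Share of cells with at least 1 UMI for the G2/M list, Pf4, Dntt, Mpo, Car1 and Hlf. Points are thinned to 1000 UMIs per cell with 95% intervals, and dashes are not thinned.

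On GRCm38 with the GENCODE M21 gene models, the sort genes Slamf1 and Cd48 lie next to each other at chr1:171767127-171801184 and chr1:171682009-171705258. Flt3 is at chr5:147330741-147400489, Kit at chr5:75574916-75656722 and Ly6a at chr15:74994877-74998031. Pf4 (chr5:90772435-90773383), Vwf (chr6:125546774-125686679), Sult1a1 (chr7:126672865-126676432) and Tgm2 (chr2:158116402-158146436) are the megakaryocyte and stem cell genes with large ratios. Dntt (chr19:41029275-41059525) and Satb1 (chr17:51736187-51833290) are the lymphoid ones, and Elane (chr10:79886247-79888215), Mpo (chr11:87793581-87804413) and Plac8 (chr5:100553725-100572245) the granulocyte-monocyte ones. Car1 (chr3:14766216-14808368), Rhd (chr4:134864536-134896172), Prss34 (chr17:25298394-25300165) and Jchain (chr5:88519809-88527891, ENSMUSG00000067149) are high in the erythroid-like cells, the basophil, mast cell and eosinophil-like cells and the Jchain-led cluster. All 18 are annotated as protein-coding.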

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

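All tests of causes in this part were chosen after the results had been seen. Small groups of cells that no marker list names stand outside the main comparisons, and each was picked out because it is low in Kit and its share in a library lies above the 0.319% that a count of 0 would allow in LT-HSC. In MPP3 these are an Ace-led cluster (5.54%, 4.39 to 6.88, 76 cells), a Jchain-led cluster (5.47%, 4.32 to 6.80, 75 cells), an Arg1-led cluster (1.68%, 1.07 to 2.5, 23 cells) and a Ccl3-led cluster (0.948%, 0.51 to 1.61, 13 cells), none of which has a cell in LT-HSC. An mt-Nd4-led cluster holds 3.57% of MPP3 (2.65 to 4.69, 49 cells) and 0.851% of LT-HSC, and its cells carry a median of 94.3% mitochondrial UMIs. In MPP2 an Fn1-led cluster holds 2.84% of cells (1.79 to 4.26, 22 cells), against 1 cell of LT-HSC. It also holds 2.66% of MPP4 (27 cells) and 1.9% of MPP3 (26 cells). Each cluster is given for the library where its share is largest, and the Ace-led one also holds 4.90% of MPP2 (38 cells). The authors' filter also fell unevenly. It fails 30.3% of erythroid-like cells (25.3 to 35.7, 96 of 317) and 33.3% of granulocyte-monocyte-like cells (27.7 to 39.3, 90 of 270). The cells outside each of these classes fail at 12.9%. Failing cells are deeper than passing ones in each library but MPP2, with medians of 5387 against 3276 UMIs in MPP3. In MPP2 the medians are 890 against 3180 UMIs. The erythroid-like and granulocyte-monocyte-like cells of MPP3 have medians of 6942 and 5562 UMIs. Whether depth rather than cell type sets the failures was not tested.

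The Jchain-led cells of MPP3 were weighed first. If Jchain were free RNA spread over the droplets like all UMIs, the cluster would hold a share of them near its 4.50% of the library's UMIs. It holds 99.1% (99.0 to 99.3). Jchain leads this cluster and was open to the clustering, so the size of that share is partly set by the choice of cluster. The value argues against an even spread over all droplets and decides nothing further. The cluster has 0.204 of the Kit CPM of the other MPP3 cells (0.097 to 0.376, 42.2 CPM against 207 CPM), but it was picked by its low Kit, so this value cannot tell whether cells with little Kit entered the Kit-positive gate. How the cells came into the library stays open. The design gives no biological explanation that could be tested, and none was.

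The megakaryocyte-like cells of LT-HSC were weighed second. Doublets with a whole HSC-like cell would keep the stem cell list above a log2 ratio of −0.62 to HSC-like cells (median depths 5749 and 3745 UMIs), and it lies at −0.92 (−1.17 to −0.82). But this list names the HSC-like class and its genes were open to the clustering, so the value cannot tell whether doublets are a cause. Scrublet called 3.9% of these cells and 1.9% of the HSC-like cells of LT-HSC. The authors' filter fails 28.0% and 7.5% of them. Cells of the MPP2 gate sorted as LT-HSC would carry like Cd48, and Cd48 is 7.5-fold higher in the MPP2 cells of the class (3.83 to 16.1, 65.8 CPM against 8.78 CPM), although cells at the low edge of CD48 stay open. Pf4 is 10.2 times that of HSC-like cells (8.34 to 12.6, 519 CPM against 50.9 CPM) when list genes are left out of the clustering, but Pf4 helps to name the cluster, so this cannot tell whether cycling cells were grouped in without megakaryocyte RNA. That stays open for the 78 of 207 cells that move to the Pbk-led cluster after thinning, with Pf4 at 157 CPM, and the 47 that move to the HSC-like class, with Pf4 at 266 CPM, against 1404 CPM in the 71 that stay.

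The lower G2/M list of ST-HSC was weighed last. Within HSC-like cells the list reads 0.13 (−0.12 to 0.25), but the list is higher by 3.08 in the other LT-HSC cells (2.80 to 3.19), so the class parts cells by the list itself and the value cannot tell whether the mix of classes is the cause. Deep cycling cells that weigh more in the sum would lose the difference after thinning, and the list stays at −0.41 (−0.61 to −0.27), which argues against that cause. The share of thinned cells with any UMI of the list shows no such difference, with 58.7% of LT-HSC and 58.4% of ST-HSC, 31.9% and 32.2% at 2 UMIs, and 75.8% and 78.4% when thinned to 2000 UMIs. What sets the list median apart from these shares was not tested.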

How the results depend on the processing

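There is 1 library per population, and no paired analysis was possible because the labels give no animal or sorting session that joins libraries. A difference between populations may thus also be one between animals, sorts or libraries, and the labels state that a first round of libraries had another final PCR step without saying which. The planned split of libraries could not be run, since the files carry 1 run and 1 library label each. Of 204 alternative values for 26 results, 146 lie within the counting interval of the main value, 57 lie outside it and 1 has the other sign. By kind, 77, 14 and 1 of 92 are list medians against LT-HSC, 36, 23 and 0 of 59 are class shares, 10, 15 and 0 of 25 are G2/M shares, and 23, 5 and 0 of 28 are MPP lists. The class shares counted here leave out the settings in which no cluster is lymphoid-like. The cause of these shifts was not tested.

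With at most 5% mitochondrial UMIs the G2/M list reads 0.17 in MPP2, 0.17 in MPP3 and 0.20 in MPP4, the megakaryocyte list of MPP2 0.29, its erythroid list 2.03, the granulocyte-monocyte list of MPP3 2.59, and that list against the other MPPs 0.68. With the authors' filter the G2/M list of MPP4 reads 0.73, the erythroid list of MPP2 2.00 and the granulocyte-monocyte list of MPP3 3.67. Against the other MPPs the filter gives 0.93 for the erythroid list of MPP2 and 0.72 for the granulocyte-monocyte list of MPP3. With each cell's CPM averaged, the G2/M list of MPP4 reads 0.64, and the megakaryocyte and erythroid lists of MPP2 read 0.33 and 2.31. Size factors give 0.63 and 0.68 for the G2/M list of MPP3 and MPP4, and 0.54 for the erythroid list of MPP2 against the other MPPs. Without clusters low in Kit the lymphoid list of MPP4 against the other MPPs is 1.15. Within HSC-like cells the G2/M list of ST-HSC turns from −0.57 to 0.13. The stem cell list of ST-HSC stays between −0.61 and −0.77 throughout.

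The megakaryocyte-like share of LT-HSC is 16.7% with the authors' filter, 18.6% with 15 components, 16.4% with no gene left out and 9.53% after thinning. In ST-HSC it is 0.27% with the authors' filter, 3.35% without list genes and 0.376% after thinning. In MPP2 it is 19.5% with no gene left out and 13.7% without list genes. In MPP3 it is 1.38% with the authors' filter, 1.09% with no gene left out and 1.39% at resolution 0.5. The HSC-like share of LT-HSC is 70.2% with the authors' filter, 73.0% with 15 components, 66.8% without list genes, 67.7% after thinning, 69.8% at resolution 0.5, 55.6% at resolution 2 and 70.8% without doublets. The granulocyte-monocyte-like share of MPP3 is 11.3% with the authors' filter and 9.69% without list genes. The lymphoid-like share of MPP4 is 27.5% with 15 components and 20.7% at resolution 2. No cluster is lymphoid-like without list genes, with the authors' filter, after thinning, without doublets or at resolution 0.5.

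The share of cells with a G2/M UMI in LT-HSC, ST-HSC, MPP2, MPP3 and MPP4 is 86.3%, 83.4%, 88.0%, 85.7% and 92.4% without thinning. It is 75.8%, 78.4%, 91.4%, 89.0% and 89.1% when cells are thinned to 2000 UMIs. With at least 2 UMIs it is 31.9%, 32.2%, 56.1%, 53.3% and 54.3%.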

Other observations

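The authors' filter and the removal of clusters low in Kit, used in this part, were chosen after the results had been seen. Immediate early, interferon response and heat shock genes were read across the populations as well. Immediate early genes are lower in MPP4 than in LT-HSC, −0.96 (−1.04 to −0.81), 12 of 17 lower, and −1.16 without the clusters low in Kit, with Nr4a1, an orphan nuclear receptor, 6.73-fold lower (6.10 to 7.43), Jund 2.74-fold and Egr1 2.34-fold lower. The list reads −0.05 in ST-HSC, 0.32 (0.23 to 0.36) in MPP2 and −0.30 (−0.33 to −0.17) in MPP3. Without the clusters low in Kit MPP2 reads 0.16, and with the authors' filter MPP3 reads −0.05 (−0.14 to 0.04). Such genes respond to handling, the labels give no order or time of the sorts, and an effect of handling was not tested. Interferon response genes are lower in MPP3, −0.75 (−0.89 to −0.46), 9 of 16, with Iigp1 6.22-fold and Ifit1 3.65-fold lower, and they read 0.08 in ST-HSC, −0.39 in MPP2 and −0.32 in MPP4. Cell cycle inhibitors go both ways, at 0.17, −0.25, −0.43 and −0.21 in ST-HSC, MPP2, MPP3 and MPP4, with 1, 2, 2 and 1 of 11 genes higher and 4, 3, 4 and 4 lower, and MPP2 reads −0.00 with the authors' filter. Within that list Cdkn1c, the p57 inhibitor, is 2.5-fold, 5.27-fold, 12.0-fold and 11.7-fold lower, and Ndn, necdin, 1.90-fold, 10.9-fold, 22.5-fold and 9.26-fold lower. In HSC-like cells alone Cdkn1c is 3.36-fold lower in ST-HSC than in LT-HSC (2.37 to 4.84). Heat shock genes read 0.03, 0.19, 0.51 and 0.17, or −0.17 in ST-HSC and 0.41 in MPP2 with the authors' filter and −0.13 in MPP4 without the clusters low in Kit, with the inducible Hsp70 gene Hspa1b 6.00-fold higher in MPP2 and 4.44-fold in MPP3.

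Genes of growth differ by small amounts. The ribosome biogenesis list reads 0.11 in ST-HSC, 0.42 (0.29 to 0.57) in MPP2, 0.33 (0.27 to 0.40) in MPP3 and 0.22 (0.19 to 0.38) in MPP4, with 1, 5, 3 and 1 of 14 genes past 1.5-fold. Myc, the growth regulator, is among them, 1.93-fold, 2.25-fold, 1.93-fold and 2.29-fold higher. Nuclear-encoded respiratory chain genes read 0.02, 0.32, 0.38 and 0.29, with 1, 5, 6 and 3 of 17 past 1.5-fold and Ndufa4 3.76-fold higher in MPP4. Glycolysis genes are near level at −0.15, 0.12, 0.07 and 0.14, although Pgk1 is 2.06-fold higher in ST-HSC and 2.11-fold in MPP3. Ribosomal protein genes have medians of −0.13, −0.20, −0.41 and −0.22, with 23 of 81 lower in MPP3, and genes from mitochondrial DNA of −0.06, −0.25, 0.08 and −0.33. The size factor shifts of at most 0.19 turn the sign of none of these 8 medians.

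Lists of other cell types were read too. The T and NK list reads 0.96 in ST-HSC, 1.06 (0.69 to 1.68) in MPP2, 0.13 in MPP3 and 0.02 in MPP4. Lck, a T cell kinase, is 2.17-fold higher in ST-HSC and 2.93-fold in MPP4. CD3e was in the depletion mix, but this list covers NK cells too. Without the clusters low in Kit it reads 0.81, 0.31, −0.51 and 0.29, from 3 or 4 genes each. Macrophage and monocyte genes read 0.01, 0.09, 0.70 and −0.29, and 0.02, −0.12, 0.00 and −0.58 without those clusters, and Ctss, cathepsin S, is 21.6-fold higher in MPP3 (15.2 to 31.7). B cell genes read −0.14, 0.41 and −0.40 in ST-HSC, MPP2 and MPP4, and −0.21, −0.07 and −0.60 without them. Stroma and endothelium genes read −0.48, −0.01, −0.75 and −0.58, with Sparc 1.74-fold lower in MPP3, and −0.47, −0.02, −0.73 and −0.68 without them. Since some of the removed clusters were named by these lists, a lower value after their removal is no evidence on what carries a list.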
